A study of Mus musculus with 9 samples.

How the data were processed

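Polyadenylated RNA from pancreatic islets of male mice was measured in 4 libraries titled as controls and 5 titled as mutants. Per the labels' protocols, RNA was extracted with a small-scale column kit and libraries were made with a low-input NEBNext kit. The growth label lists media for cells and for islets of the whole project, so the culture of these islets was not resolved. The values are whole-number counts per gene symbol, deposited by the authors without normalization. The submitters' processing notes name Bowtie2, Cell Ranger, STAR, HOMER, RSEM, R 4.1.0, DESeq2, Seurat, Signac and the mouse build mm10 for the project, without roles. Which aligner, counter and annotation made these counts, and whether counting used strand, is not given in the sources used here, so reads of close paralogs, overlapping genes and antisense partners cannot be told apart. Coordinates are those of GRCm38 (mm10) in a RefSeq gene table matched by symbol, which placed 23079 of the 23329 gene symbols. No row lacked a gene name.

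Groups and replicate numbers were taken from the sample titles and genotype labels. No pair of libraries in a group was identical within sampling noise, so none was a copy of another, and n counts libraries (4 and 5). This does not show that they come from separate animals. Totals were 6092010 to 9163253 counts per library. Shares of counts in single libraries are given with 95% Wilson intervals, and since reads carry no molecular identifiers, these cover counting error only.

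The main test, its design, the alternatives, the gene lists and the rule for named genes were set before the data were examined. Mutant was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after filterByExpr, which left 12402 genes, and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. The standard error of a log2 fold change was its unshrunken estimate divided by the square root of F. CPM values used TMM-scaled library sizes, and log2 CPM a prior count of 2. Of 40 gene lists (1038 symbols, of which 1018 were found, 19 under an older or newer symbol), the 37 with at least 5 tested members were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation called 0 lists, with 1 at an unadjusted p under 0.05, and fry, which tests whether a list's genes move on balance one way, called 7 higher and 10 lower. Cell marker levels per library (mean log2 CPM of 10 lists) were compared by exact two-sided permutation.

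Named genes were Pdx1, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, up to 3 members of lowest p per list, and a fixed set of hormone, NF-kB and clock genes. The text names part of the genes this rule gives, a few are not reported here, and any gene chosen after its values were seen is said to be so.

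Alternatives were RLE scaling, scaling without 7 hormone genes, no low-count filter, a stricter filter (CPM of at least 1 in 4 libraries), the acinar score as a covariate, the replicate number as a block, each library left out, DESeq2 1.42.0 and limma-voom with sample quality weights. After the data were seen, a fit without mutants 2 and 3 and one with the endocrine score as a covariate were added. The pipeline was tested on simulated data for the mutant against control comparison (12198 genes). Of these, 100 were changed 2-fold and 100 4-fold in either direction, and a separate gene list was raised 2-fold. It recovered 13.0% of the 100 genes changed 2-fold and 78.0% of those changed 4-fold, and 6.86% of its calls were unchanged genes.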

Results

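RNA from pancreatic islets of male mice was sequenced in 9 libraries of 2 genotypes. The labels give the genotype of 4 libraries as Pdx1+/- and title them as controls, and give the other 5, titled as mutants, the genotype Pdx1A4, which they do not explain. Pdx1 is a homeodomain transcription factor required for pancreas formation and beta cell function. The groups are called control and mutant here. Islets are small endocrine clusters in which insulin-secreting beta cells predominate beside glucagon, somatostatin and pancreatic polypeptide cells, and the surrounding exocrine pancreas consists of acinar cells, which make digestive enzymes, and ducts. The deposited counts per gene summed to between 6092010 and 7375376 per control library and between 7186462 and 9163253 per mutant library. The series title names NF-kB, the circadian clock and IL-1B therapy in connection with beta cell function, and the only contrast in these libraries is mutant against control. Nothing in the labels says that the libraries of a group come from separate animals, so p-values measure the spread between these libraries, which may be technical.

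Pdx1 (chromosome 5, positions 147270097 to 147275848 of GRCm38) was lower in all 5 mutant libraries than in any control, at 12.9 ± 6.91 CPM (counts scaled to a common library size; SD, n = 5) against 29.5 ± 5.54 (SD, n = 4). The log2 fold change was -1.19 with a standard error of 0.40 (edgeR quasi-likelihood adjusted p = 0.0461). Its log2 CPM was 5.18, 5.01, 4.59 and 4.72 in controls 1 to 4, and 3.99, 2.15, 2.89, 4.18 and 4.34 in mutants 1 to 5. The call was lost in 6 of the 9 fits that left out 1 library (controls 1 to 4, mutant 1 or mutant 3), where the adjusted p reached 0.113. Without mutants 2 and 3 together the log2 fold change of Pdx1 was smaller, at -0.78, and passed (edgeR adjusted p = 0.0268). DESeq2 gave -1.29 with all 9 libraries (adjusted p = 0.011). With the endocrine score, the mean level of insulin granule exocytosis genes, as a covariate, its log2 fold change was -0.09 (edgeR adjusted p = 0.882).

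Hormone transcripts took a smaller share of the mutant libraries, and acinar transcripts a larger one. Ins1, Ins2, Iapp, Gcg, Sst, Ppy and Pyy together held 19.1% ± 1.97 of counts in controls (SD, n = 4) and 4.25% ± 3.54 in mutants (SD, n = 5). The share was 7.99%, 0.0691%, 1.21%, 4.70% and 7.27% in mutants 1 to 5, and the 95% Wilson interval of the lowest, mutant 2, ran from 0.0674% to 0.0708%, which covers counting error only. Genes of the acinar list held 4.55% ± 1.14 in controls (SD, n = 4) and 24.3% ± 7.17 in mutants (SD, n = 5), with the highest share, 31.2%, also in mutant 2. The first principal component held 65.4% of the variance. Averaged over the hormone genes, the level lay 2.26-fold below the control mean in mutant 1, 189-fold in mutant 2, 11.5-fold in mutant 3, 2.69-fold in mutant 4 and 2.49-fold in mutant 5. These genes, of several cell types, changed by similar amounts within a library. The mean log2 change was -7.56 in mutant 2, with an SD over genes of 0.50, and -3.53 in mutant 3, with 0.23. The SD was largest in mutant 4, at 0.53 around -1.43, where Ppy changed by -0.61 and Gcg by -2.26.

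**Figure D1:**
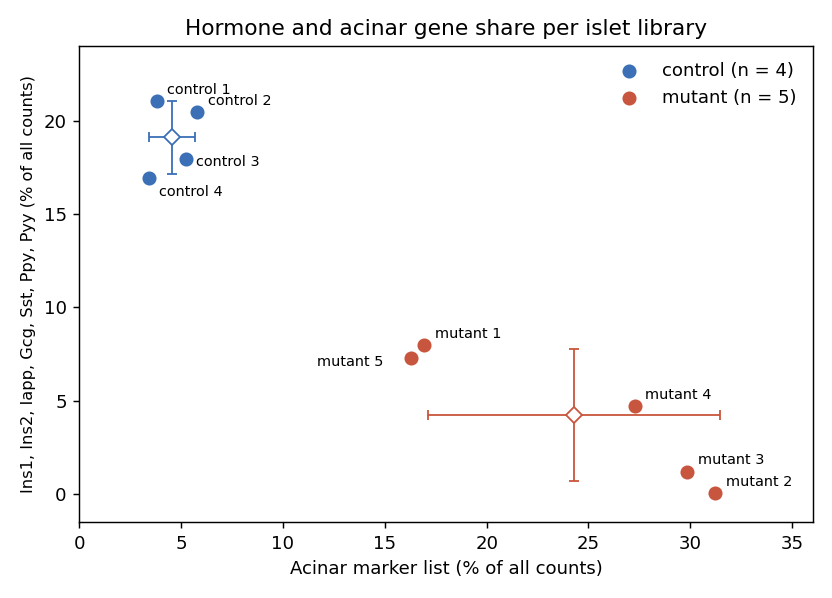
Share of all counts held by the acinar marker list (horizontal axis, percent) and by 7 islet hormone genes (vertical axis, percent) in each library; diamonds with bars are group means and SD (4 control and 5 mutant libraries). Every mutant library lies right of and below the controls, and mutant 2 has 31.2% acinar and 0.0691% hormone counts.

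Marker levels per library were compared for 10 cell type lists, as mean log2 CPM, by exact two-sided permutation over all splits of the libraries. None passed Benjamini-Hochberg adjustment, with a lowest adjusted exact p of 0.0635 and 5 lists at an unadjusted p under 0.05. The acinar score was 10.71 ± 0.510 in mutants (SD, n = 5) and 8.04 ± 0.259 in controls (SD, n = 4), higher in 5 of 5 mutant libraries than in any control (exact permutation p = 0.00794, the smallest these splits can give). The mutant minus control difference was -2.21 for beta cell identity (exact p = 0.0317), -1.65 for alpha cells (exact p = 0.0159) and -2.60 for delta cells (exact p = 0.0317), each lower in 5 of 5 mutant libraries than in any control. The gamma and epsilon cell score was 5.51 ± 2.12 in mutants (SD, n = 5) and 8.51 ± 0.248 in controls (SD, n = 4; exact p = 0.0238). The difference was 0.79 for ductal cells (exact p = 0.0794), -1.39 for endothelial cells (exact p = 0.183), -0.83 for macrophages (exact p = 0.262), -1.75 for stellate cells and fibroblasts (exact p = 0.0635) and 0.04 for Schwann cells and neurons (exact p = 0.944). Without mutant 1, 1 list was higher and 6 were lower after adjustment.

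Of 12402 genes tested, 2560 were higher and 1462 lower in mutants (edgeR quasi-likelihood test, adjusted p under 0.05), so that 63.6% of calls were higher. Scaling by relative log expression (RLE) shifted the median log2 fold change by -0.10 and gave 51.8% higher, and DESeq2 gave 49.5%. In 2295 genes every mutant library lay above every control and in 1823 below, where chance gives on average 1.59% of genes in both directions together. Genes that move together also separate together, so a count above that average does not exclude chance. Without control 1 the counts were 1678 higher and 699 lower, and without mutant 3 they were 1579 and 900. Without mutants 2 and 3, the libraries with the lowest hormone share, they were 1355 and 1229, of which 1328 and 916 were among the calls from all 9 libraries. With the endocrine score as a covariate 469 genes were higher and 64 lower. With the acinar score, which the group explained to 92.7%, as a covariate, edgeR called 0 in either direction, with 493 genes at an unadjusted p under 0.05. Of the 22 gene lists that passed camera, the glycolysis and hypoxia lists alone kept their direction and call with the acinar score. Neither passed there with an estimated correlation (camera adjusted p = 0.713 and 0.466).

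Among genes in which every mutant library lay above every control, the largest rises reported here were in Kng2, Clca1, Serpina6, Acot1, Reg3d, Cyp2c70, Klk1b4, Prss1 and Ces2c, with log2 fold changes from 4.73 (Kng2) to 3.58 (Ces2c). Kng2, a kininogen gene, had 137 ± 160 CPM in mutants (SD, n = 5) and 5.15 ± 3.17 in controls (SD, n = 4; edgeR adjusted p = 0.0136), and its log2 fold change was 2.00 without mutants 2 and 3. Clca1, Serpina6, Cyp2c70 and Prss1 had log2 fold changes of 1.54, 1.02, 2.02 and 2.04 without those libraries, against 4.34, 4.08, 3.81 and 3.65 with them, and Clca1 no longer passed (edgeR adjusted p = 0.0516). Clca1 was lost without control 1 or control 4 (highest edgeR adjusted p = 0.059), and Serpina6 without any of controls 1 to 4 (highest adjusted p = 0.063). Serpina6 was barely apart, at 5.79 log2 CPM in mutant 4 and 5.78 in control 2. With the endocrine score as a covariate, Klk1b4 and Ces2c alone of these genes passed (edgeR adjusted p = 0.0371 and 0.0410). The others did not pass there, with log2 fold changes from 2.02 (Reg3d, edgeR adjusted p = 0.124) to 0.13 (Serpina6, edgeR adjusted p = 0.959). Reg3d, Klk1b4, Prss1, Ces2c, Cyp2c70 and Acot1 belong to families of close paralogs that may share reads, so their levels are uncertain.

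The largest falls reported here among genes with the groups apart were in Cartpt, Il1b, Cnr1, Cxcl13, Ndufa4l2, Crybb3, St8sia5, Hspa1a and Hip1, with log2 fold changes from -4.24 (Cartpt) to -3.12 (Hip1). Cartpt, which encodes a neuropeptide precursor, had 0.678 ± 0.421 CPM in mutants (SD, n = 5) and 13.2 ± 5.02 in controls (SD, n = 4; edgeR adjusted p = 0.00185). The inducible heat shock protein 70 gene Hspa1a had 12.9 ± 4.08 CPM in mutants and 113 ± 37.3 in controls, a log2 fold change of -3.14 with a standard error of 0.31 (edgeR adjusted p = 0.00114). Its near-identical neighbour Hspa1b may share its reads. Cnr1, the cannabinoid receptor 1 gene, had a log2 fold change of -3.54. Its counts in mutants 1 to 5 were 6, 1, 1, 3 and 12, and those of Ndufa4l2 were 9, 0, 1, 8 and 9. St8sia5 had 2, 0, 1, 27 and 36. Near such counts the size of a fall is uncertain. St8sia5 was lost without control 1, 3 or 4 (highest edgeR adjusted p = 0.0645). With the endocrine score as a covariate, Hspa1a alone of these genes passed (log2 fold change -3.59, edgeR adjusted p = 0.00698). The others stayed lower there without passing, with log2 fold changes from -2.90 (Cartpt, edgeR adjusted p = 0.0610) to -1.25 (St8sia5, edgeR adjusted p = 0.661).

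Acinar genes rose together. Of 30 tested members 28 rose and 0 fell, as many as adjusted over the list alone, with a median log2 fold change of 3.07 (camera adjusted p = 2.56e-24; adjusted p = 0.388 with an estimated correlation). Rbpjl, a transcription factor of the acinar programme, rose from 11.3 ± 3.56 CPM (SD, n = 4) to 52.2 ± 7.55 (SD, n = 5), a log2 fold change of 2.21 with a standard error of 0.23 (edgeR adjusted p = 0.00142). Ctrl, a chymotrypsin-like protease, and Spink3, a trypsin inhibitor, had log2 fold changes of 3.10 and 3.12. In the ductal list 7 of 17 members rose and 2 fell, as many as adjusted over the list alone (camera adjusted p = 0.0385, higher; adjusted p = 0.575 with an estimated correlation). Its median log2 fold change was -0.05 and its mean 0.51, so the 2 differed in sign. The keratin genes Krt19 and Krt18 and the trefoil factor gene Tff2 rose by 2.13, 2.03 and 2.90 on the log2 scale. The ductal call was lost without control 1 (camera adjusted p = 0.0825) and with the endocrine score as a covariate (camera adjusted p = 0.138).

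Genes of endocrine identity and secretion fell. In the beta cell identity list 8 of 26 members fell and 1 rose, as many as adjusted over the list alone (median log2 fold change -1.68, camera adjusted p = 5.89e-07; adjusted p = 0.468 with an estimated correlation). DESeq2 called 19 members and limma-voom 16, in either direction. Without mutants 2 and 3 edgeR called 18 as lower and 0 as higher. Entpd3, an ectonucleotidase of the beta cell surface, had 65.2 ± 43.5 CPM in mutants (SD, n = 5) and 255 ± 31.6 in controls (SD, n = 4), and Ero1lb, an oxidase of disulfide formation, 172 ± 28.1 and 343 ± 59.6. The member that rose was Foxa2, a transcription factor of endoderm (log2 fold change 0.47, edgeR adjusted p = 0.0233), which was lost without control 1 or 2 or mutant 2, 3 or 4 (highest adjusted p = 0.0904). Ins1, Ins2 and Iapp had log2 fold changes of -1.97, -1.98 and -1.88, lower in 5 of 5 mutants than in any control, and with all 9 libraries did not pass in edgeR (adjusted p = 0.120, 0.123 and 0.111) but passed in DESeq2 (adjusted p = 0.0330, 0.0295 and 0.0293). Without mutants 2 and 3 they passed in edgeR, at -1.38, -1.40 and -1.29 (edgeR adjusted p = 0.0116, 0.0205 and 0.0112), as they did without mutant 2 alone (edgeR adjusted p = 0.0322, 0.0400 and 0.0365). Ins1 and Ins2 are close paralogs. The glucose transporter gene Slc2a2 had 10.9 ± 12.2 CPM in mutants and 19.1 ± 7.76 in controls (edgeR adjusted p = 0.481). Mafa was not tested, as it had 0 counts in all controls and 1 count in each of 2 mutant libraries. Beta cells are known to express Mafa, and whether counting or annotation lost it is open, so these values are not read as absence.

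Other hormone cells showed the same direction. In the alpha cell list 3 of 10 members fell and 0 rose, as many as adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.456 with an estimated correlation), among them Gc (log2 fold change -1.40) and Ttr (-2.20), a vitamin D binding protein and transthyretin. In the delta cell list 3 of 6 fell, or 4 adjusted over the list alone (camera adjusted p = 0.00474; adjusted p = 0.456 with an estimated correlation), among them the retinol binding protein gene Rbp4 (-1.80). Gc was lost without control 3 or 4, Ttr without controls 1 to 3 or mutants 3 to 5, and Rbp4 without any of 7 libraries (highest edgeR adjusted p = 0.0549, 0.0828 and 0.0872), while the log2 fold changes stayed between -1.67 and -1.23, -2.64 and -1.91, and -2.19 and -1.57. Gcg, Sst and Ppy had log2 fold changes of -2.20, -2.01 and -1.68 that did not pass in edgeR with all 9 libraries (adjusted p = 0.0851, 0.109 and 0.154), while DESeq2 called Gcg and Sst (adjusted p = 0.0166 and 0.0331) and limma-voom Gcg (adjusted p = 0.045). In edgeR they passed without mutants 2 and 3, at -1.64, -1.42 and -1.10. Gcg passed in edgeR also without mutant 1 (adjusted p = 0.0453) or mutant 2 (0.0256), and Sst without mutant 2 (0.0225). Of 4 tested gamma and epsilon cell genes 1 fell, Cartpt, also adjusted over the list alone.

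The secretory machinery fell with the cell markers. A smaller share of endocrine cells was not told apart from lower expression within them. Of 36 insulin granule exocytosis genes 11 fell and 0 rose, or 15 adjusted over the list alone (median log2 fold change -1.74, camera adjusted p = 1.94e-07; adjusted p = 0.456 with an estimated correlation). DESeq2 called 28 of them and limma-voom 27, in either direction, and edgeR called 25 as lower without mutants 2 and 3. Rph3al, a Rab effector of granules, fell by 2.12 on the log2 scale, Unc13a, a priming factor, by 2.92, and Ptprn2, a granule membrane protein, by 1.75. Of 23 ion channel genes of stimulus-secretion coupling 9 fell and 2 rose, or 13 and 2 adjusted over the list alone (camera adjusted p = 7.27e-05; adjusted p = 0.456 with an estimated correlation), among them the calcium channel gene Cacna1d (log2 fold change -1.68). Of 30 incretin and cAMP signalling genes 8 fell and 0 rose, or 5 adjusted over the list alone (camera adjusted p = 1.25e-05; adjusted p = 0.455 with an estimated correlation). For this list DESeq2 and limma-voom each called 19 genes in either direction, and edgeR called 9 as lower without mutants 2 and 3. Crem, a cAMP-responsive transcription factor, had 47.4 ± 9.65 CPM in mutants (SD, n = 5) and 158 ± 25.4 in controls (SD, n = 4), a log2 fold change of -1.73 with a standard error of 0.19 (edgeR adjusted p = 0.00147). The kinase subunit gene Prkar1a and the phosphodiesterase gene Pde3b fell by 1.32 and 1.57. The hormone share fell beside these groups, and with the endocrine score, which is made of the exocytosis genes, as a covariate edgeR called 1 exocytosis and 1 incretin gene. In that fit it called 0 beta cell identity and 0 ion channel genes, with 10 and 5 at an unadjusted p under 0.05. In the list of genes normally repressed in beta cells 10 of 16 rose and 0 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00118; adjusted p = 0.455 with an estimated correlation), among them Smad3 (log2 fold change 2.16) and the Hippo pathway coactivator Yap1 (2.05). The acinar share was higher in the same libraries, and with the acinar score as a covariate this call ended (camera adjusted p = 0.389). It held with the endocrine score (camera adjusted p = 0.00128; adjusted p = 0.382 with an estimated correlation). Which cells express these genes was not tested.

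**Figure D2:**
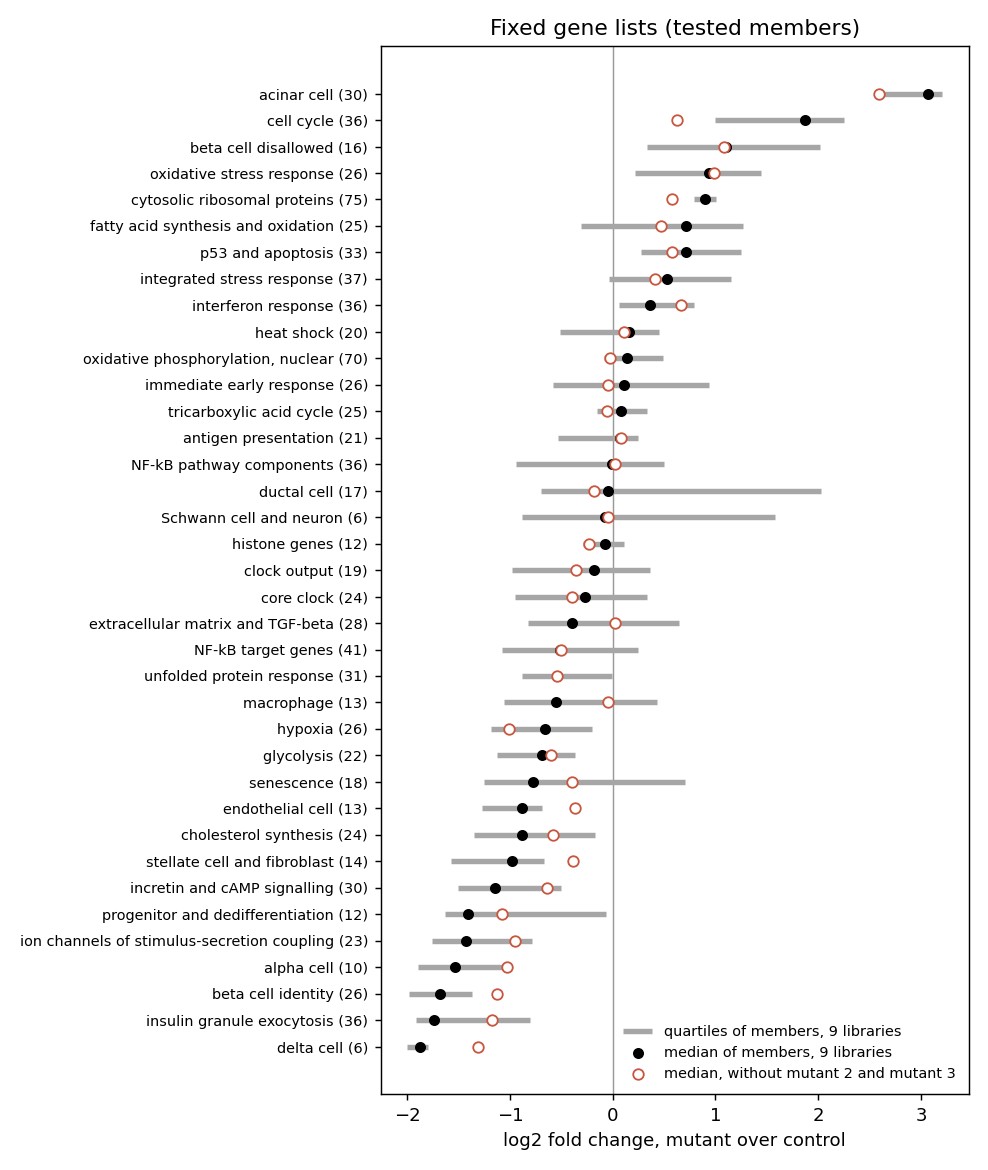
Median log2 fold change (mutant over control, horizontal axis) of the tested members of each of 37 fixed gene lists, with all 9 libraries (black points, grey bars from the lower to the upper quartile of members) and without mutants 2 and 3 (open circles). The acinar list has the highest median, 3.07, and the delta cell list the lowest, -1.87; the cell cycle median drops from 1.88 to 0.63 without the 2 libraries.

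NF-kB target genes were lower in mutants. Of 41 tested members 11 fell and 1 rose, as many as adjusted over the list alone, with a median log2 fold change of -0.51 (camera adjusted p = 0.0043; adjusted p = 0.554 with an estimated correlation). The interleukin 1 beta gene Il1b (chromosome 2) had 0.682 ± 0.624 CPM in mutants (SD, n = 5) and 8.57 ± 2.19 in controls (SD, n = 4), a log2 fold change of -3.60 with a standard error of 0.62 (edgeR adjusted p = 0.00388). Its counts in mutants 1 to 5 were 14, 0, 4, 3 and 5, so the size of its fall is uncertain. The inhibitor gene Nfkbia, which NF-kB itself induces, had 182 ± 27.8 CPM in mutants and 389 ± 110 in controls, a log2 fold change of -1.09 with a standard error of 0.21 (edgeR adjusted p = 0.00565). Tnfaip3, a ubiquitin-editing feedback inhibitor, fell by 1.21 and the cytokine gene Il6 by 2.60 on the log2 scale. The list's call was lost without control 4 (camera adjusted p = 0.0978), and with the acinar score as a covariate its direction turned to higher (camera adjusted p = 0.0435; adjusted p = 0.713 with an estimated correlation). In the fit with the endocrine score edgeR called 0 of its members, with 8 at an unadjusted p under 0.05 (Il1b -2.20, adjusted p = 0.142; Nfkbia -0.77, adjusted p = 0.118).

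Components of the NF-kB pathway moved both ways, with 8 of 36 higher and 6 lower, or 9 and 8 adjusted over the list alone (camera adjusted p = 0.535). Rela, the p65 subunit, had 45.8 ± 9.72 CPM in controls (SD, n = 4) and rose, with a log2 fold change of 1.05 with a standard error of 0.25 (edgeR adjusted p = 0.013), and 0.64 without mutants 2 and 3, where it did not pass (edgeR adjusted p = 0.0649). Ikbkg, the regulatory subunit of the IkB kinase, rose by 0.92 on the log2 scale (edgeR adjusted p = 0.00321). The kinase gene Ikbkb had a log2 fold change of 0.50 (edgeR adjusted p = 0.0304), a call lost without any of 7 libraries (controls 1 to 3 and mutants 2 to 5; highest edgeR adjusted p = 0.109). It was also lost without mutants 2 and 3, where the log2 fold change was 0.52 (edgeR adjusted p = 0.0653). Nfkb1 had a log2 fold change of -0.42 (edgeR adjusted p = 0.229). The interleukin 1 receptor gene Il1r1 had one of -1.85 (edgeR adjusted p = 0.0929) and passed with all 9 libraries in DESeq2 (adjusted p = 0.0287) and limma-voom (adjusted p = 0.0319). In edgeR it passed without mutants 2 and 3 (-1.28, adjusted p = 0.00859) or without mutant 2 alone (-1.59, adjusted p = 0.0209). Of 13 macrophage genes edgeR called 0, also adjusted over the list alone, with 4 at an unadjusted p under 0.05, 2 called by DESeq2 and 4 by limma-voom (camera adjusted p = 0.236, and 0.00632 without mutant 1).

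Per1, Per2, Cry1 and Cry2, which encode repressors of the clock, fell, while no difference was detectable in the activators Arntl and Clock. Of 24 core clock genes 7 fell and 1 rose, as many as adjusted over the list alone, and the list did not pass (median log2 fold change -0.27, camera adjusted p = 0.132). With the endocrine score as a covariate it passed as lower (camera adjusted p = 0.00153; adjusted p = 0.291 with an estimated correlation). In that fit edgeR called 1 member as lower, and Per1, Per2, Cry1 and Cry2 no longer passed (adjusted p = 0.183, 0.114, 0.120 and 0.292). Their log2 fold changes there were still negative, at -1.14, -1.68, -0.89 and -0.64. Per1 had 3.88 ± 0.274 CPM in controls (SD, n = 4) and fell, with a log2 fold change of -1.36 with a standard error of 0.32 (edgeR adjusted p = 0.0116). Per2, Cry1 and Cry2 fell by 1.21, 0.77 and 0.93, and Bhlhe40, a repressor that also responds to hypoxia, fell by 1.03. Per2 was lost without controls 1, 2 or 4 or mutants 1, 4 or 5, Cry1 without controls 1 or 4 or mutant 3, and Cry2 without controls 1 or 4 (highest edgeR adjusted p = 0.0828, 0.0654 and 0.0601). Cry1 and Cry2 also did not pass without mutants 2 and 3 (edgeR adjusted p = 0.0516 and 0.0694), where their log2 fold changes were -0.857 and -0.785. Arntl2, a paralog of the activator Arntl (Bmal1), rose by 1.93 from 1.51 ± 0.428 CPM. Arntl and Clock had log2 fold changes of 0.10 and 0.04 with standard errors of 0.19 and 0.12 (edgeR adjusted p = 0.718 and 0.808). Nr1d1 (-0.19), Nr1d2 (0.38), Dbp (0.34) and Per3 (-1.33) did not pass, and Per3 was at 7.16 log2 CPM in control 2 against 4.08 in the next control. Of 19 clock output genes 3 rose and 4 fell, as many as adjusted over the list alone (camera adjusted p = 0.346). The labels give no time of day for tissue collection.

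**Figure D3:**
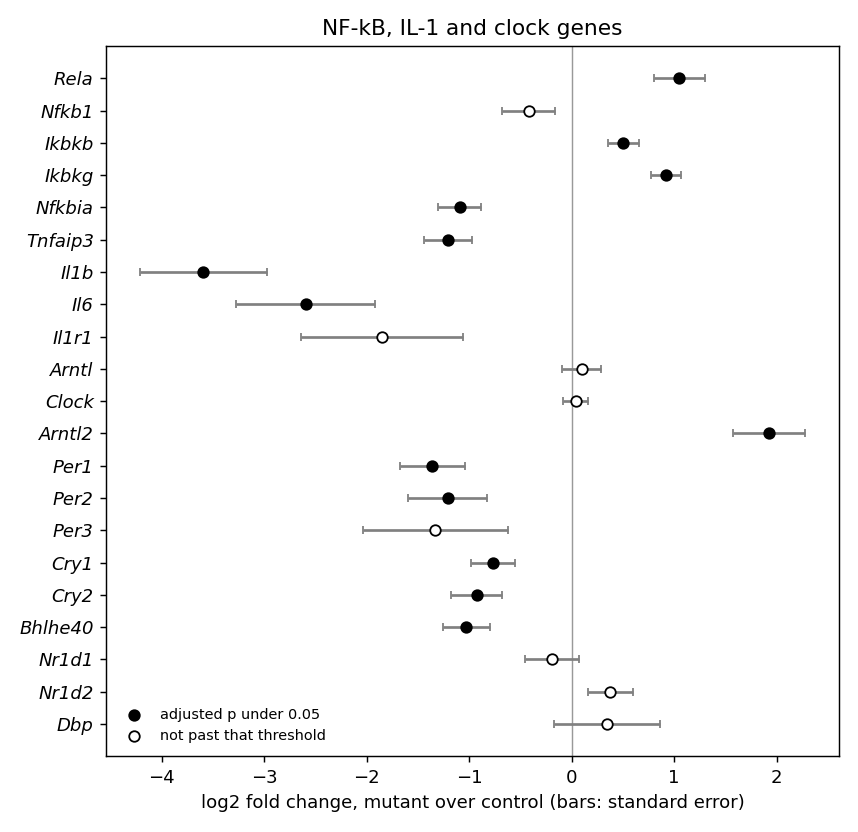
Log2 fold change (mutant over control, horizontal axis) of genes of NF-kB and interleukin 1 signalling and of the clock, with standard errors as bars; filled points passed adjusted p under 0.05 in edgeR and open points did not. Il1b lies at -3.60 and Arntl2 at 1.93, while Arntl and Clock lie at 0.10 and 0.04.

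Hypoxia and glycolysis genes fell. Of 26 hypoxia genes 11 fell and 1 rose, as many as adjusted over the list alone, with a median log2 fold change of -0.66, and -1.01 without mutants 2 and 3 (camera adjusted p = 1.25e-05; adjusted p = 0.455 with an estimated correlation). The mitophagy receptor gene Bnip3 had 243 ± 69.5 CPM in mutants (SD, n = 5) and 982 ± 133 in controls (SD, n = 4), a log2 fold change of -2.01 with a standard error of 0.24 (edgeR adjusted p = 0.00152). P4ha1, a collagen prolyl hydroxylase, and Egln1, an oxygen-sensing prolyl hydroxylase, fell by 2.45 and 1.73 on the log2 scale. Of 22 glycolysis genes 9 fell and 0 rose, as many as adjusted over the list alone (camera adjusted p = 7.27e-05; adjusted p = 0.455 with an estimated correlation), among them the phosphofructokinase genes Pfkp (log2 fold change -2.23) and Pfkl (-1.23) and the mutase gene Pgam1 (-1.28). With the endocrine score as a covariate 7 hypoxia and 4 glycolysis genes passed as lower, not all of them among the genes above, and the lists share members such as Pgam1.

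Other metabolic lists split. Of 24 cholesterol synthesis genes 7 fell and 1 rose, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.456 with an estimated correlation), with Pmvk and Lss falling by 1.98 and 1.30 on the log2 scale. Of 25 genes of fatty acid synthesis and oxidation 12 rose and 3 fell, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.00896; adjusted p = 0.455 with an estimated correlation), and the lipid droplet gene Plin2 rose by 2.03. Of 75 cytosolic ribosomal protein genes 70 rose and 0 fell, or 73 adjusted over the list alone, with a median log2 fold change of 0.89 that was 0.57 without mutants 2 and 3, where 34 rose (camera adjusted p = 1.36e-15; adjusted p = 0.456 with an estimated correlation). The acinar share was higher and the hormone share lower in the same libraries. With the endocrine score as a covariate edgeR called 2 of the 75 ribosomal genes (median 0.47), and the cholesterol and fatty acid calls were lost (camera adjusted p = 0.0600 and 0.114). With the acinar score the ribosomal list turned to lower (median -0.50, camera adjusted p = 0.000623; adjusted p = 0.713 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes that may share their reads. In the nuclear oxidative phosphorylation list 14 of 70 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.236, and 0.00921 without control 2), and in the tricarboxylic acid cycle list 5 of 25 rose and 2 fell, as many as adjusted over the list alone (camera adjusted p = 0.914).

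Stress responses differed by kind. Oxidative stress genes rose, with 16 of 26 higher and 1 lower, as many as adjusted over the list alone (median log2 fold change 0.94, camera adjusted p = 1.78e-05; adjusted p = 0.455 with an estimated correlation). Nfe2l2, which encodes the antioxidant regulator NRF2, had 359 ± 50.7 CPM in mutants (SD, n = 5) and 129 ± 13.2 in controls (SD, n = 4), a log2 fold change of 1.48 with a standard error of 0.15 (edgeR adjusted p = 0.00142). Gclc, of glutathione synthesis, rose by 2.88, and the cystine transporter gene Slc7a11 by 1.97. In the integrated stress response list 18 of 37 rose and 2 fell, or 23 and 5 adjusted over the list alone (camera adjusted p = 0.000841; adjusted p = 0.456 with an estimated correlation). Cth, of cysteine synthesis, rose by 2.15, while Atf4, the list's transcription factor, had a log2 fold change of 0.37 that did not pass (edgeR adjusted p = 0.117). In the unfolded protein response list 13 of 31 fell and 3 rose, or 16 and 4 adjusted over the list alone (camera adjusted p = 0.00263, lower; adjusted p = 0.455 with an estimated correlation). Its members moved apart, as the oxidase gene Ero1l fell by 1.12 and the sensor kinase gene Eif2ak3 rose by 1.53. Of 20 heat shock genes 6 rose and 3 fell, as many as adjusted over the list alone (camera adjusted p = 0.914). The acinar share was higher in the same libraries, and with the acinar score as a covariate the calls of the oxidative stress (median -0.04, camera adjusted p = 0.426), integrated stress (0.128) and unfolded protein lists (0.181) ended. The integrated stress call also ended with the endocrine score (camera adjusted p = 0.0600).

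Of 33 p53 and apoptosis genes 17 rose and 1 fell, or 18 and 2 adjusted over the list alone (camera adjusted p = 7.42e-05; adjusted p = 0.455 with an estimated correlation), with the p53 targets Ccng1 and Phlda3 rising by 1.63 and 1.83 on the log2 scale. Of 36 cell cycle genes 20 rose and 1 fell, or 26 and 1 adjusted over the list alone (median log2 fold change 1.88, camera adjusted p = 0.000174; adjusted p = 0.554 with an estimated correlation), including the replication genes Cdc6 (2.21) and Mcm3 (1.41). Without mutants 2 and 3 the cell cycle median was 0.63 and 3 genes rose. The hormone and acinar shares differed beside this list, and with the endocrine score as a covariate its call was lost (median 0.36, camera adjusted p = 0.819), with 0 genes called by edgeR and 5 at an unadjusted p under 0.05. With the acinar score it turned to lower (median -1.55, camera adjusted p = 0.0243; adjusted p = 0.713 with an estimated correlation), and the p53 call ended (camera adjusted p = 0.702). Stellate cell and fibroblast genes were lower as a list, with 2 of 14 falling, or 1 adjusted over the list alone (camera adjusted p = 0.00474; adjusted p = 0.554 with an estimated correlation), among them the collagen gene Col1a2 (log2 fold change -2.55), lost without control 1 (adjusted p = 0.0557); the list did not pass without mutants 2 and 3 (adjusted p = 0.0728). The endothelial list passed as lower with 0 of 13 members called by edgeR, also adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 called by DESeq2 and 3 by limma-voom (camera adjusted p = 0.0178; adjusted p = 0.655 with an estimated correlation), and not without control 4 (0.0806), mutant 2 (0.0712) or mutants 2 and 3 (0.336).

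The remaining lists did not pass with all 9 libraries and no covariate. Of 36 interferon response genes 1 rose and 2 fell, or 0 in either direction adjusted over the list alone by edgeR, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.971). This list passed as higher without mutants 2 and 3 (median log2 fold change 0.66, camera adjusted p = 0.0169; adjusted p = 0.745 with an estimated correlation). It also did with the endocrine score as a covariate (median 1.13, camera adjusted p = 0.000904; adjusted p = 0.720 with an estimated correlation). Of 21 antigen presentation genes 1 rose, or 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.387, and 0.0244, lower, without mutant 4). Of 26 immediate early genes 6 rose and 5 fell, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.864). In the list of progenitor and dedifferentiation genes 2 of 12 rose and 2 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.131). Of 18 senescence genes 1 rose and 3 fell, as many as adjusted over the list alone (camera adjusted p = 0.136), and of 28 genes of extracellular matrix and TGF-beta signalling 4 rose and 2 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.651). Of 12 histone genes 1 fell, also adjusted over the list alone (camera adjusted p = 0.346). In the list of Schwann cell and neuron genes 2 of 6 rose, as many as adjusted over the list alone, with a median log2 fold change of -0.07 and a mean of 0.35 (camera adjusted p = 0.605, higher). Only 2 lymphocyte genes were tested, too few for camera, and 0 passed in edgeR or limma-voom, with 1 adjusted over the list alone and 1 by DESeq2. None of the 13 mitochondrially encoded genes listed was in the count table.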

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

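The tests of explanations in this part were all chosen after the results were seen, while the comparison of each library with the others of its group was planned. Among 210 groups of values 15 had a library far from the rest, where chance gives about 5%. In the mutants, mutant 1 had a Krt19 log2 CPM of 9.90, below the nearest at 10.39, an Hspa1a value of 2.66, an Ikbkg value of 6.30, an Nr1d1 value of 2.98 and a Phlda3 value of 5.78, each the lowest. Mutant 2 had a Cartpt value of -1.92, which stands for 0 counts. Mutant 4 had a Cth value of 5.35. Mutant 5 had an Ero1lb value of 7.80, a Per1 value of 1.49 and a hypoxia score of 5.21, against 5.77 in the nearest library. In the controls, control 1 had an Nfe2l2 value of 6.78, control 2 a Foxa2 value of 4.79 and a Per3 value of 7.16, against 4.08 in the nearest library, control 3 a Crybb3 value of 6.72 and control 4 a Schwann cell and neuron score of 3.22.

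Acinar markers were higher and endocrine markers lower in every mutant library. A smaller endocrine share, with all other cells in unchanged proportion, would raise every other cell type alike. The acinar score instead rose against the endothelial score by 4.05 (exact permutation p = 0.0159). It rose against the macrophage score by 3.49 and against the stellate score by 4.41. Where those cells belong to the islets, a smaller share of islets would lower them too, so these values do not argue against that. The endothelial, macrophage and stellate scores were each lowest in mutant 2, the library of lowest hormone share. A change in beta cells alone would leave alpha cells as they were, and the alpha cell score differed by -1.65 (exact permutation p = 0.0159, adjusted 0.0635). More exocrine tissue carried through the islet preparation may account for it and cannot be told apart from an effect of the genotype, since the group explains 92.7% of the variance in the acinar score and no library of one group reaches the other. Of 100 splits, 1, the real one, gave 4022 genes, with 3 in the highest other. A split that mixes the groups puts their difference inside its arms and so leaves few genes to call. This count therefore does not exclude chance for the genes. For the 22 lists chance cannot be excluded either, as 16 of 100 splits gave as many and the highest other gave 25.

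Hypoxia genes were lower in the mutants. A first comparison used covariates, where the list stayed lower with the endocrine score (camera adjusted p = 9.57e-15, and adjusted p = 0.291 with an estimated correlation) and with the acinar score (1.84e-11, and adjusted p = 0.466 with an estimated correlation). After those values were seen it was replaced by slopes within groups, with a bound of 0.5 of the slope needed, since acinar cells may express such genes themselves. The 11 genes that fell had a median slope of 0.05 on the endocrine score (quartiles -0.05 to 0.23, needed 0.71). For these genes that argues against a smaller endocrine share as the whole cause. They were picked by passing in the same libraries, which favours genes steady within groups, and the slope rests largely on mutants 2 and 3. The 8 beta cell identity genes picked in the same way had a median slope of 0.85 (needed 0.9). The score is itself made of islet secretory genes, so a slope near that needed was likely in advance. It shows that genes with a slope can pass, and not that the picking left the hypoxia slope unbiased. For the 11 hypoxia genes the slope on the acinar score was 0.03 (quartiles -0.27 to 0.28, needed -0.48), too widely spread to decide. A larger acinar share therefore cannot be told apart from an effect of the genotype.

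NF-kB target genes were lower in the mutants. Here too a first comparison with covariates (camera adjusted p = 0.00762, lower, with the endocrine score and 0.0435, higher, with the acinar score, and adjusted p = 0.720 and 0.713 with an estimated correlation) was replaced by slopes within groups after those values were seen. The 11 genes that fell had a median slope of 0.30 on the endocrine score (quartiles 0.14 to 0.66, needed 0.67) and of -0.43 on the acinar score (quartiles -0.64 to -0.16, needed -0.45). Their mean fell short of separating from the macrophage score, with a difference of -0.83 (exact permutation p = 0.0635). A smaller endocrine share, a larger acinar share and fewer macrophages may each account for the pattern and cannot be told apart from an effect of the genotype on these cells.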

How the results depend on the processing

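The fits without mutants 2 and 3 and with the endocrine score were chosen after the result was seen, and all others were planned. The counts of 2560 higher and 1462 lower genes became 0 and 0 with the acinar score as a covariate (edgeR, 493 at an unadjusted p under 0.05), 469 and 64 with the endocrine score, and 1355 higher without mutants 2 and 3. DESeq2 gave 2617 lower and limma-voom 2294. Leaving out each library gave 1579 to 2702 higher and 699 to 1865 lower, with the lowest counts without mutant 3 (1579 and 900) and control 1 (1678 and 699). With a replicate block they were 1658 and 774, and no list call changed. The numbers were not read as pairs, as the labels do not say what they mark. Same-numbered libraries correlated at 0.05, -0.02, 0.18 and -0.05. No control correlated best with the mutant of its own number, and of the mutants only mutant 3 did so with its control. The lists, 9 higher and 13 lower, became 0 and 0 with an estimated correlation. With the acinar score 10 were higher and 7 lower, of which glycolysis and hypoxia alone had passed in that direction without it. The endocrine score gave 6 higher and 5 lower, of which the interferon response and the core clock had not passed before. With an estimated correlation 0 lists passed in either covariate fit or without mutants 2 and 3 (lowest adjusted p = 0.466 with the acinar score, 0.247 with the endocrine score and 0.235 without those libraries). At the preset correlation, leaving out each library gave 8 to 10 and 11 to 14. Marker lists past the threshold, 0 with all libraries, were 0 to 1 higher and 0 to 6 lower, the highest without mutant 1.

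With the acinar score, which hardly varies apart from the group, the direction turned in 19 lists that passed with or without it, and in further lists that passed in neither fit. It turned to higher, with camera adjusted p, for beta cell identity (0.00158), alpha cells (0.342), delta cells (0.342), endothelial cells (0.000204), macrophages (0.000204), stellate cells (0.0280), exocytosis (0.0415), ion channels (0.0273), incretin signalling (0.0728), cholesterol synthesis (0.151), NF-kB targets (0.0435), senescence (0.0366) and extracellular matrix (0.000143). It turned to lower for acinar cells (0.396), oxidative phosphorylation (1.53e-12), ribosomal proteins (0.000623), fatty acid metabolism (0.908), oxidative stress (0.426) and cell cycle (0.0243). Among lists that had passed, the endocrine score turned to higher beta cell identity (0.530), delta cells (0.837), endothelial cells (0.0875) and stellate cells (0.648), and some lists that passed in neither fit turned too. Besides the lists that turned, the calls gained at the preset correlation, none of which held with an estimated correlation where that was run, were the interferon response, higher, without mutants 2 and 3 (0.0169) and with the endocrine score (0.000904), the core clock, lower, with the endocrine score (0.00153), and, with the acinar score, Schwann cells and neurons, higher (0.0129), antigen presentation, lower (2.91e-05), and immediate early genes, lower (0.0055). Leaving out 1 library gained oxidative phosphorylation, higher, without control 2 (0.00921), macrophages, lower, without mutant 1 (0.00632) and antigen presentation, lower, without mutant 4 (0.0244).

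Of the 72 named genes that passed, 59 passed in all 9 fits that left out a library, 13 were lost in at least 1, and none changed sign. They kept direction and call in 71 cases with DESeq2, 68 with limma-voom, 70 with RLE scaling, 66 without mutants 2 and 3, 29 with the endocrine score and 62 with the block. With the acinar score none of the 72 passed, and 24 of them also turned in direction. Log2 fold changes there were 0.81 for Pdx1, -0.33 for Tff2, 0.14 for Unc13a, 0.53 for Cacna1d, 1.15 for Entpd3, 1.17 for Ttr, 0.80 for Rbp4, 0.74 for Pde3b, 0.63 for Prkar1a, 0.53 for Cxcl13, 0.51 for Crybb3, 1.07 for Hip1, -0.045 for Rela, 0.495 for Tnfaip3, 0.11 for Per1, 0.41 for Cry1 and 0.655 for Cry2. For the rises they were -5.95 in Kng2, -5.63 in Clca1, -5.35 in Serpina6, -0.82 in Acot1, -3.91 in Reg3d, -2.57 in Cyp2c70 and -2.58 in Prss1. The cause was not tested. Simulated 2-fold changes were mostly missed, in data where far fewer genes changed than the 4022 called here, which makes the adjusted threshold stricter. Some changes under 2-fold did pass in the real fit, such as Foxa2 (log2 fold change 0.47). The simulated recovery is therefore no measure of this comparison, and small changes may still be undetected.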

Other observations

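The genes here and their tests were all chosen only after their values were seen. Clu, which encodes the secreted chaperone clusterin, held 3.78% ± 0.577 of counts in mutants (SD, n = 5) and 0.860% ± 0.445 in controls (SD, n = 4), and rose by 2.52 on the log2 scale (edgeR adjusted p = 0.00397). In the Reg family, secreted lectins of the exocrine pancreas, 5 genes that rose were picked, with no test of the family, with log2 fold changes of 3.11 for Reg1, 3.53 for Reg2, 3.18 for Reg3b, 3.16 for Reg3g and 3.13 for Reg3a (edgeR adjusted p from 0.00539 to 0.00989). They are close paralogs, so their single levels are uncertain. Without mutants 2 and 3 these were 1.97, 2.71, 1.94, 2.03 and 2.83. The epithelial keratin genes Krt8 and Krt23 rose by 2.08 and 3.08, and the imprinted gene Mest by 3.37. The urocortin 3 gene Ucn3, a marker of mature beta cells, had a log2 fold change of -2.22 (edgeR adjusted p = 0.0639, DESeq2 adjusted p = 0.0123), and the glucose transporter gene Slc2a1 one of -0.08 (edgeR adjusted p = 0.824).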
